A study of Mus musculus with 21 samples.

How the data were processed

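The data are 21 QuantSeq 3′ mRNA-seq libraries of primary mouse hepatocytes, 1 file each, and groups were taken from the agent and dose in the labels. Per the submitters' processing notes, cutadapt 1.15, HISAT2 2.1.0 and featureCounts were used with mouse build mm10; their settings, the strand setting, the annotation release and the filter on low genes are not given in the sources used here. The deposited values are CPM scaled by the authors, since each file sums to 1000000 over the same 9657 genes. Every value in every library was a whole number of reads within 0.001 reads (100% of values), which gave back the read counts and totals of 14158740 to 37410773 reads per library. These totals cover the genes in the files, not all sequenced reads. A 3′ method counts about 1 position per transcript, so values depend on the annotated 3′ ends, and reads of genes with overlapping ends or with near-identical copies can be assigned to the wrong gene. Gstp1 and Gstp2, for example, had a ratio of 1.00 over all libraries.

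Gene identifiers were matched to GENCODE annotation of GRCm38, the assembly of mm10. Of the 9657 identifiers 9652 matched a symbol, and the set holds 8584 protein coding genes and 744 pseudogenes. The lowest mean of a gene was 1.22 CPM, and no further filter was applied.

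The planned test was edgeR's quasi-likelihood test on counts. Because the deposited unit is CPM, limma 3.58.1 in R 4.3.3 replaced it, on log2(CPM + 1), with 7 group means, all 21 libraries, a trended and robust variance prior and no covariate. Adjustment was by Benjamini-Hochberg over all genes of a comparison, with a threshold of 0.05. A fold change on this scale understates the change of genes with low CPM. Intervals of differences are 95% intervals from the same fit. Comparisons were each agent and dose against PBS, agents against each other at the same dose, 2 µM against 0.2 µM within an agent, the interactions of dose and agent, and the mean of the treated groups against PBS. The groups, tests, gene lists, naming rule and most alternatives were fixed before the data were examined.

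Of 26 gene lists 25 had at least 5 measured members and were tested with camera at a preset correlation of 0.01, with Ttr left out and adjustment over the lists of a comparison. The members named per list had the smallest p, up to 4 if past the threshold and otherwise up to 2. Ttr was named everywhere, and Rbp4, Alb, Asgr1 and Ago2 in comparisons with PBS. With 30 or fewer genes past the threshold all were named. With more, the 12 largest rises and 12 largest falls were named among called genes with a mean of at least 10 CPM whose groups did not overlap, and predicted genes were counted only. Some results that this rule selects are not reported here. Groups of 3 against 3 fail to overlap by chance for 10% of genes.

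Alternatives were edgeR 4.0.16 with TMM factors or with DESeq2 size factors and DESeq2 1.42.0 on the recovered reads, CPM rescaled with TMM factors, pseudocounts of 0.5 and 5, a minimum mean of 10 CPM, fits on only the libraries compared, the replicate number as a block, each library left out in turn, and the farthest pair of libraries left out. An alternative with no filter is the analysis as run. On lists, an estimated correlation, fry and the replicate block were tried. Between CPM as deposited, TMM factors and DESeq2 size factors the median fold change of all genes moved by less than 0.1 (log2), and 0 list medians changed sign under TMM among lists called by camera.

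Sites of 7 bases taken from the Ttr mRNA were searched in the longest annotated 3′UTR of 8556 other genes. The fold changes were fitted on UTR length and GC content, and the lowest z was compared with 1000 draws of as many 7-mers.

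The limma step was tested on simulated data for TTR-1236 at 2 µM against PBS, with 9657 genes of which 200 were changed. It recovered 24% of the genes changed 2-fold and 98% of those changed 4-fold, with 5 unchanged genes called. Reads were drawn with an assumed dispersion and without shared differences between libraries, so these rates may not hold for the real data. Small counts here may still leave room for undetected changes of about 2-fold. The 7-mer test was checked on 100 simulations of unchanged fold changes over 8556 genes, of which 11 gave a p under 0.05 with draws that exclude the 7-mers of Ttr and 5 with draws from all 7-mers. Replicates were compared before averaging, and the closest pair differed by a chi-square per degree of freedom of 25.1, well beyond sampling noise.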

Results

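Primary mouse hepatocytes, wild-type liver cells kept in culture, received PBS or 1 of 3 RNAi agents directed against Ttr, named TTR-1236, TTR-1186 and Reference 4 in the labels. Ttr encodes transthyretin, a protein that the liver secretes and that carries thyroid hormone and retinol-binding protein in blood. Each agent was given at 0.2 µM and at 2 µM, RNA was taken on Day 1, and expression was measured by QuantSeq, which reads the 3′ ends of polyadenylated RNA. The 21 libraries formed 7 groups of 3. Each library held between 14158740 and 37410773 reads over the genes in the files, and the PBS libraries held 14324315, 19109736 and 26340870. Levels are CPM, reads scaled to a sum of 1000000 in each library, given as the mean ± SD of the 3 libraries of a group. Log2 fold changes are given with their standard error on the scale of log2(CPM + 1), tested with limma over all 21 libraries, and a gene is said to have risen or fallen where its Benjamini-Hochberg adjusted p was under 0.05. The labels do not say that the libraries of a group came from separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical.

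Ttr fell under every agent at both doses. In mm10 the gene (ENSMUSG00000061808) lies on the plus strand of chromosome 18, from 20665280 to 20674321. Its level was 2258 ± 84.7 CPM in PBS. With TTR-1236 it was 8.58 ± 2.90 CPM at 0.2 µM and 13.3 ± 4.95 CPM at 2 µM, which were 0.380% and 0.590% of the PBS mean. With TTR-1186 it was 7.09 ± 3.42 CPM and 11.02 ± 3.78 CPM, or 0.314% and 0.488%. With Reference 4 it was 13.3 ± 7.17 CPM and 19.2 ± 7.25 CPM, or 0.587% and 0.848%. The log2 fold changes against PBS were -7.93 and -7.37 for TTR-1236, -8.24 and -7.60 for TTR-1186, and -7.48 and -6.87 for Reference 4, each with a standard error of 0.42, and their adjusted p-values in limma lay between 1.96e-11 and 8.23e-10. Single treated libraries held 59 to 585 Ttr reads. The lowest was a TTR-1186 library at 0.2 µM with 3.19 CPM (exact 95% Poisson interval 2.43 to 4.12), and the highest a Reference 4 library at 2 µM with 27.1 CPM (24.8 to 29.6). These intervals cover counting error only, since the reads are PCR products without molecular identifiers.

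**Figure D1:**
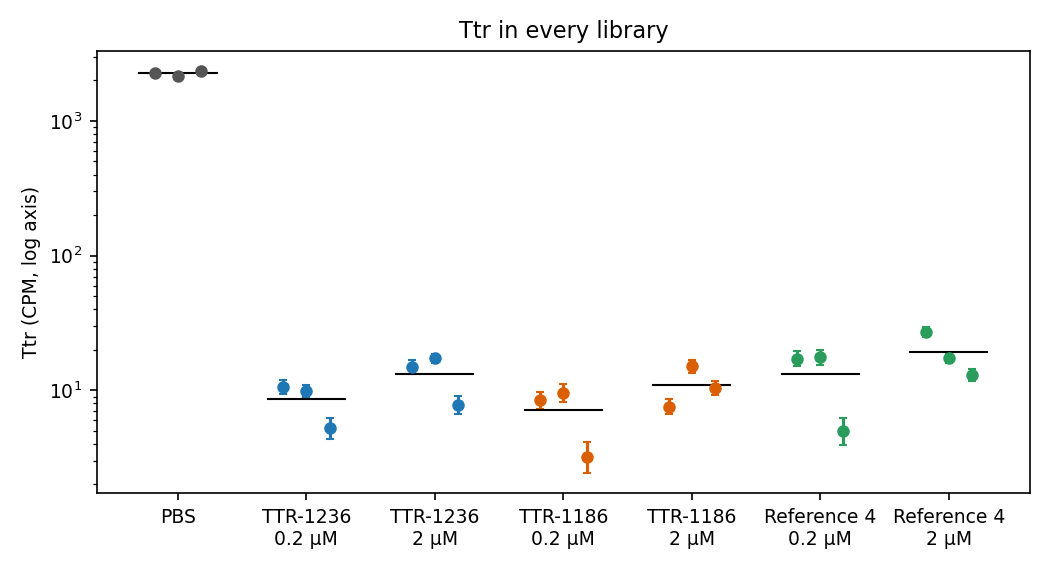
Ttr in each of the 21 libraries, in CPM on a log axis, by group; points are libraries with exact 95% Poisson intervals and horizontal lines are group means. The PBS libraries sit between 2168 and 2336 CPM and the 18 treated libraries between 3.19 and 27.1 CPM.

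Differences in residual Ttr between agents at a matched dose did not pass the threshold. At 0.2 µM the log2 difference was -0.45 (95% interval -1.32 to 0.42) for TTR-1236 against Reference 4, -0.76 (-1.63 to 0.11) for TTR-1186 against Reference 4, and 0.30 (-0.57 to 1.17) for TTR-1236 against TTR-1186. At 2 µM the corresponding differences were -0.50 (-1.37 to 0.37), -0.73 (-1.60 to 0.14) and 0.23 (-0.64 to 1.10). Both TTR-1236 and TTR-1186 thus had lower mean Ttr than Reference 4 at both doses, with intervals that all included 0 and reached beyond a 2-fold difference. Adjusted p-values in limma for these 6 differences were between 0.503 and 1.00, which does not show that the agents act alike. Mean Ttr was higher at 2 µM than at 0.2 µM for each agent, by a log2 difference of 0.56 (-0.31 to 1.43) for TTR-1236, 0.63 (-0.23 to 1.504) for TTR-1186 and 0.61 (-0.26 to 1.48) for Reference 4, none past the threshold. The dose differences of Ttr also did not differ detectably between agents, with log2 interactions of -0.05 (-1.28 to 1.18) for TTR-1236 less Reference 4, 0.02 (-1.20 to 1.253) for TTR-1186 less Reference 4, and -0.07 (-1.30 to 1.16) for TTR-1236 less TTR-1186.

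Outside Ttr, TTR-1236 at 0.2 µM moved a single gene against PBS. Igfbp1, which encodes a liver-secreted binder of insulin-like growth factors, fell from 386 ± 38.4 to 193 ± 9.46 CPM (log2 fold change -0.99 ± 0.18, adjusted p = 0.0495), and 0 genes rose. Among gene lists fixed before the data were examined, mRNAs encoded by mitochondrial DNA ranked higher than other genes (11 of 13 members higher, camera adjusted p = 4.27e-06). In that list 0 members passed over all genes and 4 rose when adjusted over the list alone, with mt-Co1 at 5629 against 3138 CPM and mt-Cytb at 974.6 against 625 CPM. Members of the unfolded protein and integrated stress response list ranked lower (19 of 29, adjusted p = 0.00662), with Hspa5, an ER chaperone, at 557 against 824 CPM. The NF-kB and inflammation list (10 of 12 lower, 0.0377), the cell cycle list (12 of 16 lower, 0.0353) and the acute phase list (19 of 28 lower, 0.0383) did so too. With an estimated correlation between genes these 5 lists had an adjusted p of 0.395 or 0.563, and fry, which tests only whether a list moves one way on balance, called 0 lists. At an unadjusted p under 0.05 limma held 665 genes, and on reads recovered from the CPM edgeR called 1 gene and DESeq2 14, of which 7 were higher. The Igfbp1 call ended in 5 of the 6 fits that left out 1 library, all except the fit without PBS replicate 3, which called 63 genes. The other 5 fits called 1 gene each, as did the fit on only the 6 libraries compared (Igfbp1 adjusted p = 0.108).

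TTR-1186 at 0.2 µM lowered Ttr, Igfbp1 and Fga, and 0 genes rose. Igfbp1 fell to 157 ± 39.2 CPM (log2 fold change -1.32 ± 0.18, adjusted p = 5.88e-04). Fga, the alpha chain of fibrinogen, fell from 237 ± 11.7 to 107 ± 12.01 CPM (-1.15 ± 0.16, adjusted p = 9.57e-04). Both calls held whichever library was left out, but ended in the fit on only the 6 libraries compared (adjusted p = 0.283 for Igfbp1 and 0.217 for Fga), which called 1 gene, Ttr. The NF-kB and inflammation list ranked lower, with 10 of 12 members lower, 0 past over all genes and 7 when adjusted over the list alone (camera adjusted p = 6.81e-04, adjusted p = 0.160 with an estimated correlation). Its leading members by p were Vcam1, an adhesion molecule, at 2.97 against 9.10 CPM and Tnfaip2 at 3.99 against 12.7 CPM. The acute phase list, the liver proteins of inflammation, also ranked lower, with 23 of 28 members lower and 5 fallen when adjusted over the list alone (3.85e-04, adjusted p = 0.255 with an estimated correlation). Mitochondrially encoded mRNAs ranked higher (12 of 13, 0.00382, adjusted p = 0.598 with an estimated correlation). Under TMM scaling 2 genes rose beside 3 that fell, against 0 and 3 with CPM as deposited, and without PBS replicate 3 the count was 41.

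Reference 4 at 0.2 µM changed 16 genes, 3 upward and 13 downward. Igfbp1 fell to 144 ± 9.59 CPM (log2 fold change -1.41 ± 0.18, adjusted p = 1.92e-04) and Fga to 119 ± 17.2 CPM (-0.99 ± 0.16, adjusted p = 0.00732). Ccl2, a chemokine that draws monocytes, fell from 64.6 ± 7.79 to 20.6 ± 4.02 CPM (-1.61 ± 0.30, adjusted p = 0.0229), and the kinase gene Jak1 from 288 ± 28.0 to 184 ± 12.3 CPM (-0.64 ± 0.13, adjusted p = 0.0430). Vcl, which encodes the focal adhesion protein vinculin, changed by -1.26, Tinagl1 by -2.17, Gtf2a2, a general transcription factor subunit, by -1.64, Aacs by -1.48, Uhmk1 by -1.10 and H6pd by -1.09. Pkn3 (-1.59) and Zdhhc12 (-1.54) overlap at their ends on chromosome 2, and without a stated strand setting their reads cannot be assigned with certainty. Hps4 (2.37) and Ankrd23 (1.68) rose, as did 1 predicted gene. All 12 measured members of the NF-kB and inflammation list were lower, 1 past over all genes and 5 when adjusted over the list alone (camera adjusted p = 3.16e-04, adjusted p = 0.0951 with an estimated correlation). The cell cycle list ranked lower in 14 of 16 members, with Cdt1 at 4.75 against 12.8 CPM and Ccnd1 at 14.97 against 31.5 CPM, neither past the threshold (4.19e-04, adjusted p = 0.482 with an estimated correlation). Of the 14 named genes besides Ttr, Igfbp1 alone passed whichever library was left out, and Fga was lost without PBS replicate 1 (adjusted p = 0.0683) and with only the 6 libraries compared (0.265), where 2 genes were called. The count was 2, 6 and 175 without PBS replicates 1, 2 and 3, and 3 and 29 without Reference 4 0.2 µM replicates 2 and 3.

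At 2 µM of TTR-1236, 139 genes rose and 472 fell, with at least a 2-fold change in 47 and 346 of them. Among those that rose were Gipc1, a PDZ-domain trafficking adaptor, from 7.76 ± 1.89 to 31.2 ± 7.40 CPM (log2 fold change 1.88 ± 0.30, adjusted p = 0.00210), Selenbp2 (1.20), Hfe, a regulator of iron uptake (from 7.17 to 19.0 CPM), Uvrag, an autophagy factor (1.23), Gstk1 (1.14) and Uox, the urate oxidase gene (1.07). U2af1l4 (1.42), Sumf1 (1.19), Wdr45 (1.17), the antisense transcript AI507597 (1.52) and the pseudogene Atp5l-ps1 (to 29.7 CPM) rose as well. Apob, the structural protein of very low density lipoprotein, fell from 218 ± 101 to 35.6 ± 15.2 CPM (-2.53 ± 0.44, adjusted p = 0.00633). Apob also varied between libraries of the same treatment. In PBS it was at 283, 270 and 102 CPM in replicates 1, 2 and 3, the last with 0.797% mitochondrial ribosomal RNA. With TTR-1186 at 2 µM it was at 128, 41.2 and 121 CPM, and replicate 2 had 0.622%. The highest library at 2 µM of TTR-1236 had 51.8 CPM. Resf1 (-2.51), Ankrd12 (-2.50) and the golgin gene Golga4 (-2.34) fell likewise, and so did the mitochondrial ribosomal RNA mt-Rnr2 (-2.33 ± 0.57, adjusted p = 0.0297). The other falls named by rule were readings of pseudogenes, Hspa9-ps1 (-3.70), AC133509.1 (-3.82), Hspd1-ps3 (-3.10), Mup-ps13 (-2.49), Morf4l1-ps1 (-2.39) and Cdv3-ps (-2.37), which share sequence with their parent genes and are uncertain. Some of these falls moved by over 1.5 times with 1 library. AC133509.1 stood at -4.67 and -3.08 without TTR-1236 2 µM replicates 1 and 3 and Ankrd12 at -1.82 without replicate 1. Without PBS replicate 3 Hspd1-ps3 stood at -3.70, Cdv3-ps at -3.07 and mt-Rnr2 at -2.94. Of the 611 genes 108 were predicted genes and 113 pseudogenes.

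Cytosolic ribosomal protein genes were the list that camera called at 2 µM of TTR-1236, with 75 of 87 members higher, 6 risen both over all genes and when adjusted over the list alone, and 0 fallen (adjusted p = 1.69e-09, adjusted p = 0.309 with an estimated correlation). Rpl12 went from 708 to 1010 CPM (0.51 ± 0.12) and Rpl10 from 1516 to 2196 CPM (0.53 ± 0.12). Members of other lists passed without the list being called. In the acute phase list Mt1, a metallothionein, rose from 4615 to 7393 CPM (0.67 ± 0.15) and Saa3 by 0.72, while the haemoglobin binder Hp changed by -0.88 and ceruloplasmin, Cp, by -1.07. In the interferon response list Parp14 (-1.28) and the RNA sensor Ddx58 (-1.19) fell and Zbp1 rose (1.58). Srebf2, the regulator of sterol synthesis genes, fell by 1.35 together with Mvd (from 106 to 53.6 CPM) and Hmgcs1 (-0.64), 3 of 27 members of the cholesterol list. Cyp3a11 (0.73) and Cyp3a13 (0.59) rose among 26 cytochrome P450 and xenobiotic genes. In the stress lists Atf5 (-1.02) and Hspa5 (-0.69) fell, and Tut4 (-2.07, and -2.68 without TTR-1236 2 µM replicate 1) and Ddx6 (-0.95) fell among 21 RNAi machinery genes. Of 54 named genes besides Ttr, 7 passed whichever library was left out, namely Gipc1, Hspa9-ps1, Apob, Resf1, Golga4, Hp and Cp. Hp and Cp were lost with only the 6 libraries compared (adjusted p = 0.0742 for both). The count was 49, 46 and 1588 without PBS replicates 1, 2 and 3, 206 and 63 without TTR-1236 2 µM replicates 2 and 3, and 22 with only the 6 libraries compared. The share of mitochondrial ribosomal RNA (mt-Rnr1 and mt-Rnr2) was 0.412% of all CPM in this group and 2.25% in PBS.

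TTR-1186 at 2 µM changed 5 genes. Jak1 fell from 288 ± 28.0 to 165 ± 8.07 CPM (log2 fold change -0.80 ± 0.13, adjusted p = 0.0120), Igfbp1 to 174 ± 29.5 CPM (-1.15 ± 0.18, adjusted p = 0.00539) and Ypel2 from 24.6 ± 5.81 to 7.09 ± 3.66 CPM (-1.75 ± 0.33, adjusted p = 0.0359). The mitochondrial transfer RNA mt-Ty rose from 92.2 ± 11.9 to 185 ± 43.8 CPM (0.97 ± 0.18, adjusted p = 0.0359). Ribosomal protein genes ranked higher in 79 of 87 members (camera adjusted p = 8.56e-08, adjusted p = 0.325 with an estimated correlation), with 0 past the threshold singly and Rpl6 at 994 against 783 CPM. The culture dedifferentiation and cytoskeleton list ranked higher in 27 of 36 members (5.63e-04, adjusted p = 0.365 with an estimated correlation), with Acta1 at 54.1 against 23.2 CPM, and so did 6 of 8 stellate cell and fibroblast markers (0.0177, adjusted p = 0.325 with an estimated correlation), of which 5 rose when adjusted over the list alone. The interferon response list (28 of 37 lower, 0.0255, adjusted p = 0.630 with an estimated correlation) and the acute phase list (21 of 28 lower, 0.0210, adjusted p = 0.365 with an estimated correlation) ranked lower. Igfbp1 was lost without PBS replicate 1 (adjusted p = 0.0916) and with only the 6 libraries compared (0.221), where 1 gene, Ttr, was called. Jak1 was lost in 3 of the 6 fits without 1 library, and Ypel2 and mt-Ty in 4. The count was 1 and 37 without PBS replicates 1 and 3, 13 and 2 without TTR-1186 2 µM replicates 1 and 3, and 0 genes rose and 3 fell in edgeR with TMM factors.

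Reference 4 at 2 µM raised 57 genes and lowered 160, of which 15 and 115 changed at least 2-fold. Mt1 rose from 4615 ± 367 to 8162 ± 1660 CPM (log2 fold change 0.81 ± 0.15, adjusted p = 0.0130) and Hamp, which encodes the iron hormone hepcidin, from 11.5 ± 6.40 to 34.5 ± 10.3 CPM (1.61 ± 0.41, adjusted p = 0.0382). Gipc1 (to 24.4 CPM), Dlec1 (1.60), Gstp3 (1.28), Cipc (1.18), polyubiquitin Ubb (0.86), the cytokine gene Mif (0.86), Serpina1d (0.84), Tkfc (0.83), Saa3 (0.82) and the pseudogene Rpl15-ps2 (0.85) also rose. Apob, which varied within PBS as given above, fell to 34.9 ± 4.81 CPM (-2.48 ± 0.44, adjusted p = 0.0131). Rbm28, a nucleolar RNA-binding protein gene, fell from 52.0 ± 20.4 to 12.3 ± 1.93 CPM (-1.92 ± 0.32, adjusted p = 0.00544). The Notch ligand gene Jag1 (-2.30), Bod1l (-2.24), Ankrd12 (-1.96), Man2a1 (-1.95), the endosomal tether gene Eea1 (-1.84), Resf1 (-1.84), Bdp1 (-1.74) and Lyst (-1.72) fell, as did the pseudogene Hspa9-ps1 (-3.99). Jag1 stood at -1.70 and -3.09 without PBS replicates 1 and 3, and Eea1 at -2.43 without PBS replicate 3. Of the 217 genes 37 were predicted genes and 35 pseudogenes.

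Hepatocyte secreted protein and identity genes ranked higher at 2 µM of Reference 4, with 27 of 36 members higher, 2 risen and 1 fallen over all genes, and 7 and 1 when adjusted over the list alone (camera adjusted p = 0.00772, adjusted p = 0.0438 with an estimated correlation). Serpina1d and Apoc3 (0.75) rose while Apob fell. The acute phase list went up on balance (18 of 28 higher, 0.00772, adjusted p = 0.406 with an estimated correlation), with 4 members risen and 2, Hp (-0.79) and Cp (-0.91), fallen, and with 10 and 3 when adjusted over the list alone. Cholesterol synthesis and uptake genes ranked lower in 20 of 27 members, with Mvd (-1.30) and Hmgcs1 (-0.74) fallen and 7 fallen when adjusted over the list alone (0.0220, adjusted p = 0.402 with an estimated correlation). Ribosomal protein genes ranked higher in 72 of 87 members, with Rps18 (0.61) and Rpl10 (0.47) risen and 5 when adjusted over the list alone (4.88e-07, adjusted p = 0.402 with an estimated correlation), and mitochondrially encoded mRNAs in 10 of 13 (0.0304, adjusted p = 0.760 with an estimated correlation). Mitochondrial ribosomal RNA took 0.767% of CPM against 2.25% in PBS. Of 35 named genes besides Ttr, Hspa9-ps1 alone passed whichever library was left out. The count was 6, 9 and 1272 without PBS replicates 1, 2 and 3, 66, 98 and 10 without Reference 4 2 µM replicates 1, 2 and 3, and 40 with only the 6 libraries compared.

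The genes called against PBS at 2 µM of TTR-1236 and of Reference 4 overlapped in 44 risen and 111 fallen genes besides Ttr, and 0 genes went opposite ways. The size of this overlap depended on single libraries. Without PBS replicates 1, 2 and 3 it was 0 and 4, 0 and 6, and 241 and 764 genes, without TTR-1236 2 µM replicates 1, 2 and 3 80 and 150, 15 and 50, and 5 and 36, and without those of Reference 4 10 and 45, 15 and 53, and 2 and 7. In each of these 9 fits 0 genes went opposite ways. The fold changes of the 2 comparisons, which share the PBS libraries, correlated across genes, which are not independent replicates, at r = 0.846, with a covariance of 0.277. Unchanged groups simulated from resampled residuals, with a control group shared by both comparisons, gave a median of 0.497 and 0.0573 over 100 draws.

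**Figure D2:**
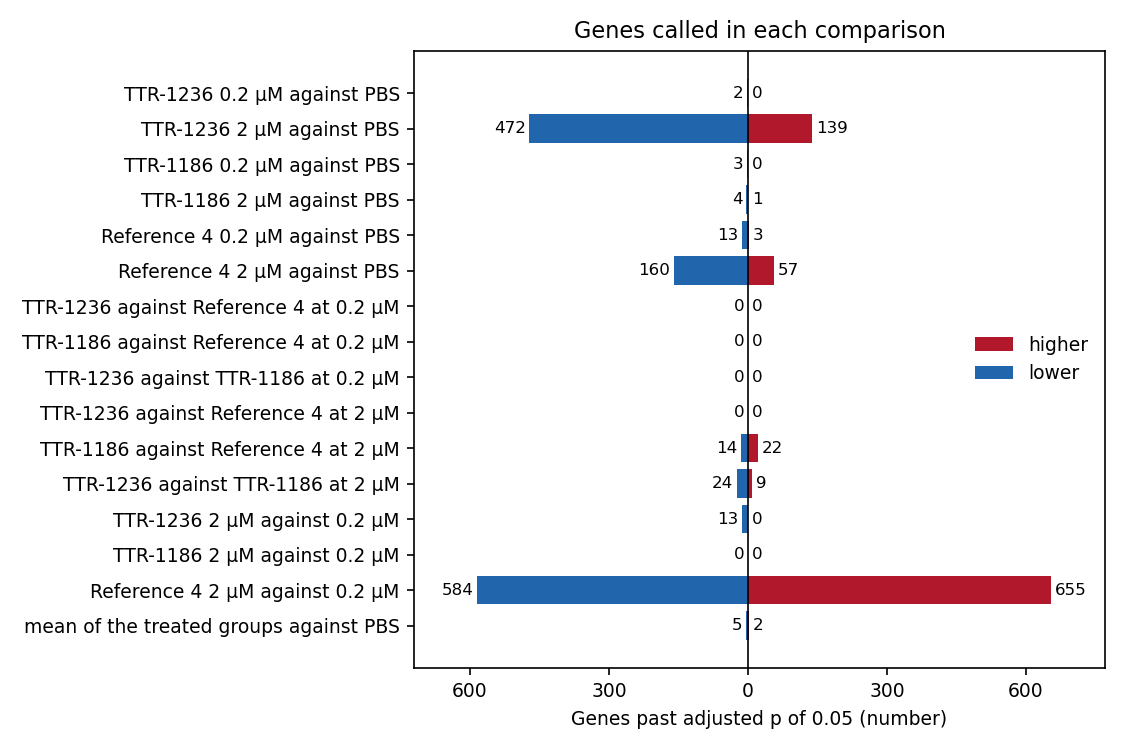
Number of genes past an adjusted p of 0.05 in limma in each of 16 comparisons, with higher genes to the right and lower genes to the left of 0. The largest bars are Reference 4 at 2 µM against 0.2 µM (655 higher, 584 lower) and TTR-1236 at 2 µM against PBS (139 higher, 472 lower).

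Averaged over all 6 treated groups, Jak1, Raver2, Hp and Igfbp1 fell with Ttr, and Gipc1 and 1 predicted gene rose. Jak1 encodes a kinase of cytokine receptors and was below the lowest PBS library (256.0 CPM) in 18 of 18 treated libraries, of which the highest had 199 CPM (log2 fold change -0.81 ± 0.10, adjusted p = 2.0e-04). By group its level was 180 ± 15.6 and 132 ± 18.02 CPM at 0.2 and 2 µM of TTR-1236, 195 ± 5.18 and 165 ± 8.07 CPM with TTR-1186, and 184 ± 12.3 and 137 ± 9.63 CPM with Reference 4. Raver2 (-0.96 ± 0.17, adjusted p = 0.0184) was also below every PBS library in 18 of 18, but its annotated 3′ end overlaps that of Jak1 on the opposite strand of chromosome 4, so the pair may share reads. Hp fell from 5123 ± 332 to 3318 CPM (-0.64 ± 0.11, adjusted p = 0.0191; 18 of 18 libraries lower), Igfbp1 by 0.85 (adjusted p = 0.00607; 15 of 18), and Gipc1 rose by 1.22 (adjusted p = 0.0280). By camera the NF-kB list (10 of 12 lower, adjusted p = 0.0199), the unfolded protein response list (22 of 29 lower, 0.0447) and the cell cycle list (12 of 16 lower, 0.0447) ranked lower, and stellate markers (7 of 8, 0.00942), mitochondrially encoded mRNAs (11 of 13, 0.00942) and ribosomal proteins (61 of 87, 1.53e-04) higher. With an estimated correlation the adjusted p of these 6 lists was 0.434, 0.517 or 0.617, and 0 of their members passed over all genes. Jak1 passed whichever library was left out, Raver2 (adjusted p = 0.222), Hp (0.281) and Igfbp1 (0.149) did not without PBS replicate 1, and Gipc1 failed in 2 such fits, with an adjusted p of up to 0.303. The count was 3, 14 and 639 without PBS replicates 1, 2 and 3, 12 without TTR-1236 0.2 µM replicate 1, 22 and 11 without TTR-1236 2 µM replicates 1 and 2, and 11 without Reference 4 2 µM replicate 1 or TTR-1186 2 µM replicate 2. The TMM-scaled CPM gave 8 higher and 4 lower genes against 2 and 5.

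**Figure D3:**
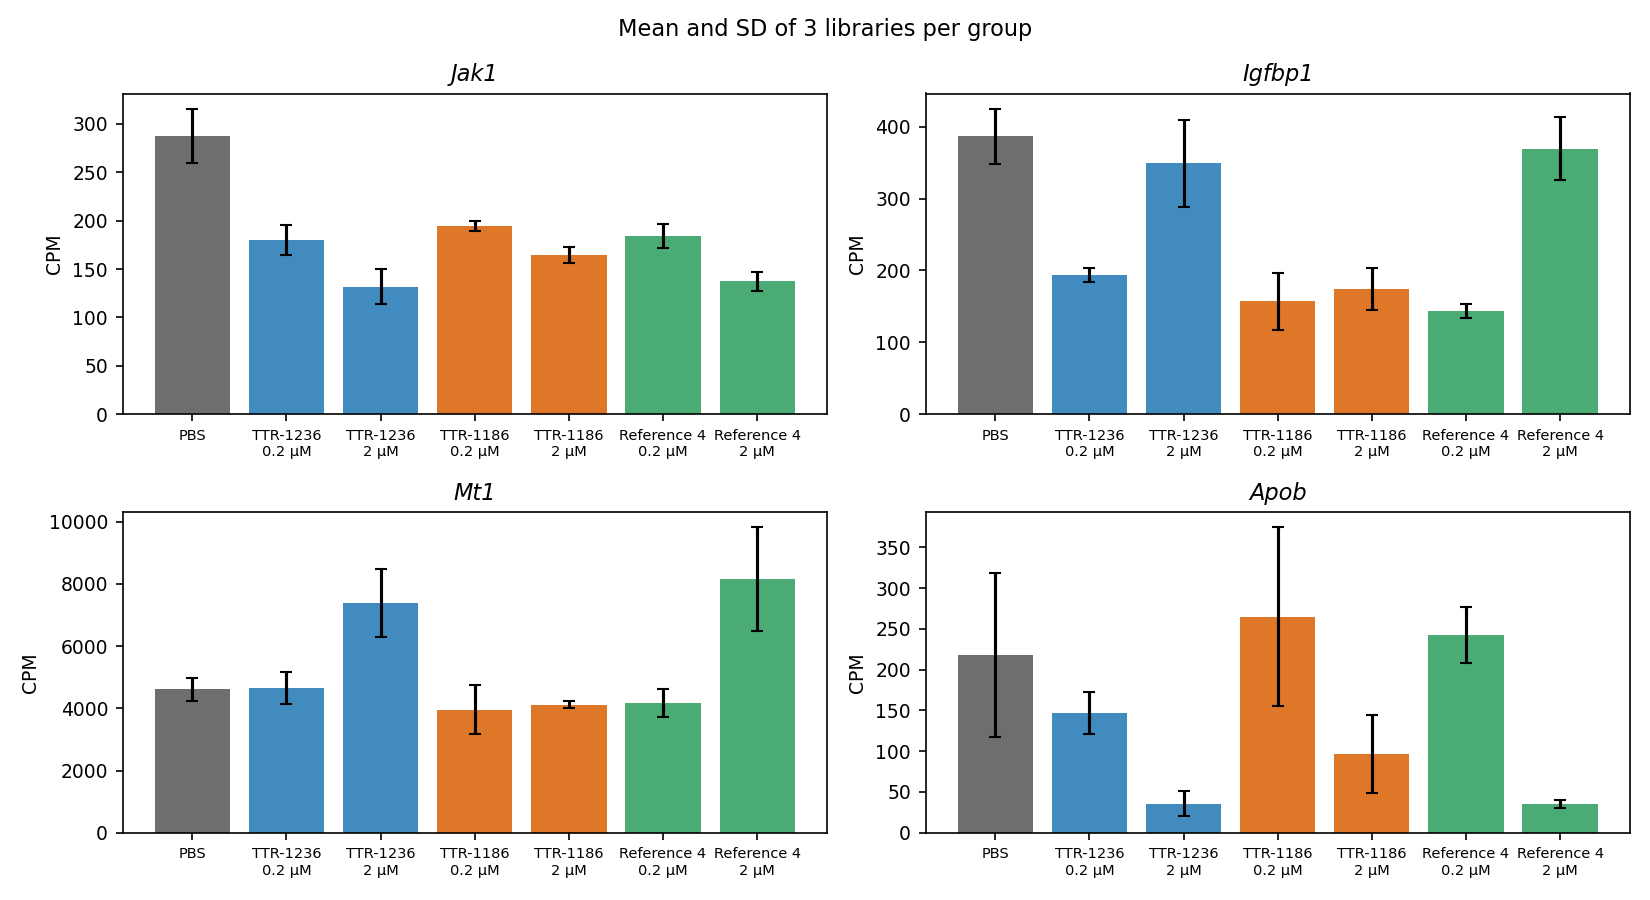
Jak1, Igfbp1, Mt1 and Apob in the 7 groups, in CPM on linear axes from 0; bars are means and error bars SDs of 3 libraries. Jak1 is lower in every treated group than in PBS (288 CPM), Igfbp1 is near its PBS level of 386 CPM at 2 µM of TTR-1236 (349 CPM) and of Reference 4 (369 CPM), and Mt1 and Apob move in those same groups. Apob also varies within PBS (218 ± 101 CPM).

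Of 4 genes named in every comparison with PBS beside Ttr, 1 passed the threshold. Rbp4, the retinol carrier that binds transthyretin, rose at 2 µM of TTR-1236 (874 ± 31.6 to 1160 ± 137 CPM, log2 fold change 0.40 ± 0.11, adjusted p = 0.0386) and of Reference 4 (1193 ± 47.6 CPM, 0.45 ± 0.11, adjusted p = 0.0409). The first of these calls ended in 4 and the second in 5 of the 6 fits without 1 library. Albumin, Alb, was at 5182 ± 728 CPM in PBS and between 3662 and 6388 CPM in treated groups, and that was not past the threshold. The asialoglycoprotein receptor gene Asgr1 was at 69.5 ± 9.70 CPM in PBS and lowest at 0.2 µM of TTR-1186 (40.7 ± 5.83 CPM, adjusted p = 0.370). The argonaute gene Ago2 was at 81.3 ± 17.3 and 78.3 ± 24.0 CPM at 2 µM of TTR-1236 and Reference 4 against 129 ± 17.3 CPM in PBS (adjusted p = 0.0523 and 0.0534). Markers of other liver cells were sparse. Of 24 Kupffer cell and macrophage markers 5 were measured, led by Cd68 at 105 CPM, of 25 sinusoidal endothelial markers 6, led by Egfl7 at 75.1 CPM, of 18 cholangiocyte markers 9, led by Bicc1 at 148 CPM, and of 26 lymphocyte and blood cell markers 1, Alas2 at 10.3 CPM. Camera called none of the first 3 lists in the 6 comparisons with PBS, with lowest adjusted p-values of 0.249, 0.0794 and 0.497. Of 25 stellate cell and fibroblast markers 8 were measured, led by Ecm1 at 73.9 CPM, and that list was called at 2 µM of TTR-1186 (0.0177, adjusted p = 0.325 with an estimated correlation, median log2 fold change 0.74). The lists of lipogenesis (lowest adjusted p = 0.552), heat shock (0.464), immediate early genes (0.0603), p53 response (0.259), miR-122 targets (0.288), asialoglycoprotein receptor and endolysosome (0.179), retinol and thyroid hormone transport (0.409), PPAR-alpha and fatty acid oxidation (0.474), RNAi machinery (0.137), NRF2 oxidative stress (0.246) and cytochrome P450 genes (0.0513) were not called there either.

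Between agents at 0.2 µM, limma called 0 genes in all 3 comparisons. For TTR-1236 against Reference 4 the smallest adjusted p was 0.0701, held among others by Tubb2a, a tubulin gene, at 189 against 94.0 CPM, and mt-Atp6, a subunit of mitochondrial ATP synthase, at 3355 against 2023 CPM. There 1351 genes had an unadjusted p under 0.05, edgeR called 0, DESeq2 238, limma on only the 6 libraries compared 499, and the fit without Reference 4 0.2 µM replicate 3 called 18. Cytochrome P450 genes (21 of 26 higher, led by Cyp3a11 at 302 against 173 CPM), cytoskeletal genes (23 of 36) and mitochondrially encoded mRNAs (8 of 13) ranked higher, each with a camera adjusted p of 0.0403 and an adjusted p of 0.643, 0.727 and 0.727 with an estimated correlation. For TTR-1186 against Reference 4, 475 genes had an unadjusted p under 0.05, edgeR and DESeq2 called 0, and the fit without Reference 4 0.2 µM replicate 3 called 2. Interferon response genes (29 of 37, camera adjusted p = 6.0e-04) and acute phase genes (20 of 28, 0.00390) ranked lower, and cytoskeletal (27 of 36, 6.98e-04), cell cycle (13 of 16, 0.00267), cholesterol (20 of 27, 0.00390) and NRF2 genes (20 of 23, 0.0127) higher. All 6 had an adjusted p of 0.276 with an estimated correlation, and ribosomal proteins, lower in 55 of 87 (0.0127), had 0.753. For TTR-1236 against TTR-1186, 685 genes had an unadjusted p under 0.05, edgeR called 0 and DESeq2 3. Cytochrome P450 genes (21 of 26, 0.0144) and ribosomal proteins (65 of 87, 6.24e-05) ranked higher, both with an adjusted p of 0.606 with an estimated correlation.

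At 2 µM, TTR-1186 differed from Reference 4 in 36 genes, 22 higher and 14 lower. Metallothionein Mt1 was lower with TTR-1186 (4114 ± 119 against 8162 ± 1660 CPM, log2 difference -0.97 ± 0.15, adjusted p = 0.00465), and so were Igfbp1 (174 against 369 CPM, -1.09 ± 0.18, adjusted p = 0.00613), Fabp1, the liver fatty acid-binding protein (9.35 against 43.3 CPM, -2.09 ± 0.40, adjusted p = 0.0208), and Hpd, an enzyme of tyrosine breakdown (9.73 against 47.5 CPM, -1.96 ± 0.36, adjusted p = 0.0208). Gnmt (-1.27), the zinc importer Slc39a14 (16.2 against 38.6 CPM), the interferon regulator Irf7 (-1.05), Bnip3 (-1.01), Cdo1 (-0.83), Lcn2 (-0.79) and Atp5g2 (-0.75) were lower as well, although Atp5g2 read nearly the same as the predicted gene Gm10175 over all libraries (ratio 1.06). Fdps, an enzyme of the mevalonate pathway, was higher (374 against 208 CPM, 0.84 ± 0.13, adjusted p = 0.00465), as were Sox4 (226 against 104 CPM, 1.11), Irf2 (1.42), Bod1l (1.95), Ttc3 (1.23), Acbd3 (1.16) and the pseudogenes Hspa9-ps1 (3.07), AC144860.3 (1.37) and Amd-ps3 (1.12). Ppp2r5b (128 against 53.8 CPM) and Gpha2 (1.24) overlap on chromosome 19, and Bc1 and Lrrc17 (1.80 each) moved together from different chromosomes, so these pairs are uncertain. Acute phase genes were lower on balance in TTR-1186 (25 of 28, 2 past over all genes and 12 lower when adjusted over the list alone, camera adjusted p = 2.53e-09, adjusted p = 0.0195 with an estimated correlation). Hepatocyte secreted protein and identity genes were lower too (26 of 36, 1 and 7, 4.83e-07, adjusted p = 5.64e-04 with an estimated correlation), and cholesterol genes higher (23 of 27, 1 and 3, 5.51e-05, adjusted p = 0.0338 with an estimated correlation). Interferon response genes ranked lower (28 of 37, 5.51e-05) and cytoskeletal genes higher (21 of 36, 0.0214), with an adjusted p of 0.403 and 0.697 with an estimated correlation. Hspa9-ps1 and Fdps passed whichever library was left out, and Mt1 and Igfbp1 were lost only without Reference 4 2 µM replicate 1 (adjusted p = 0.0665 for both). The count was 2 and 8 without Reference 4 2 µM replicates 1 and 3, and 10 without TTR-1186 2 µM replicate 3. The share of mitochondrial ribosomal RNA also differed, at 1.59 ± 0.852% with TTR-1186 and 0.767 ± 0.361% with Reference 4.

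TTR-1236 differed from TTR-1186 at 2 µM in 33 genes, 9 higher and 24 lower. Mt1 (7393 ± 1101 against 4114 ± 119 CPM, log2 difference 0.83 ± 0.15, adjusted p = 0.0121), Igfbp1 (349 against 174 CPM, 1.00 ± 0.18, adjusted p = 0.0121), Hpd (1.74), Selenbp2 (1.75), Bnip3 (1.00), Cdo1 (0.84) and Actl6a (1.11) were higher with TTR-1236. Ptma, which encodes prothymosin alpha, was lower (195 ± 23.8 against 422 ± 79.8 CPM, -1.10 ± 0.19, adjusted p = 0.0121), as were Sox4 (-1.15), Fdps (-0.68), Atxn2 (-2.24), Birc6 (-1.57), Wbp11 (-1.45), Acp1 (-1.23), Scoc (-1.13), Hspa9-ps1 (-2.79) and the uncertain pairs Bc1 and Lrrc17 (-1.97 and -1.94) and Ppp2r5b and Gpha2 (-1.33 and -1.31). Hepatocyte identity genes were higher on balance (24 of 36, 1 past over all genes, 6 higher and 2 lower when adjusted over the list alone, camera adjusted p = 3.30e-04, adjusted p = 0.00776 with an estimated correlation). Acute phase genes ranked higher in 25 of 28 members (1 and 5, 1.5e-05, adjusted p = 0.115 with an estimated correlation). Of the 20 named genes 0 passed whichever library was left out. The count was 170, 2 and 1 without TTR-1236 2 µM replicates 1, 2 and 3, and 181 and 8 without TTR-1186 2 µM replicates 2 and 3. The share of mitochondrial ribosomal RNA differed here too, at 0.412 ± 0.116% with TTR-1236 and 1.59 ± 0.852% with TTR-1186.

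Between TTR-1236 and Reference 4 at 2 µM limma called 0 genes, edgeR 0 and DESeq2 1, and 288 genes had an unadjusted p under 0.05. Interferon response genes ranked lower with TTR-1236 (30 of 37, camera adjusted p = 6.91e-06, adjusted p = 0.449 with an estimated correlation), with Oasl1 at 20.1 against 38.3 CPM and Bst2 at 121 against 205 CPM, and 2 members lower when adjusted over the list alone. Cholesterol genes ranked higher (18 of 27, 6.64e-04, adjusted p = 0.191 with an estimated correlation) and mitochondrially encoded mRNAs lower (12 of 13, 0.0390, adjusted p = 0.705 with an estimated correlation).

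Reference 4 at 2 µM differed from Reference 4 at 0.2 µM in 1239 genes, 655 higher and 584 lower. The change was at least 2-fold in 305 and 388 of them. Of the NF-kB and inflammation list 3 of 12 members rose and 0 fell, without the list being called (camera adjusted p = 0.0599). They were Ccl2, from 20.6 to 71.6 CPM (log2 difference 1.74 ± 0.30, adjusted p = 0.00224), the chemokine Cxcl1 (1.81) and Vcam1 (1.27). Acute phase genes that rose included Mt1 from 4167 to 8162 CPM (0.96 ± 0.15, adjusted p = 0.00157), Fga (0.97), Serpina3n (1.03) and Lcn2 (0.70). In the acute phase list 8 of 28 members rose and 0 fell over all genes, and 9 and 1 when adjusted over the list alone (camera adjusted p = 0.00178, adjusted p = 0.454 with an estimated correlation). Hepatocyte genes Alb (3662 to 6388 CPM, 0.80 ± 0.14, adjusted p = 0.00224), Serpinc1 (0.65) and Serpina1d (0.77) rose, and so did Cyp27a1 (1.58), Cyp2f2 (0.90), Cyp2e1 (2.36) and Fabp1 (1.71). In the hepatocyte list 6 of 36 members rose and 2 fell (0.0404, adjusted p = 0.205 with an estimated correlation), among the latter Apob (243 ± 34.3 to 34.9 ± 4.81 CPM, -2.76 ± 0.44, adjusted p = 0.00224). Cell cycle genes were not called as a list (4 of 16 risen, 0 fallen, Cdt1 by 1.66 and Pcna by 1.26 among them, 0.1002). Nor were unfolded protein response genes (4 of 29 risen, such as Xbp1 by 1.21, and 3 fallen, such as Atf5 at -0.75, 0.657). Ribosomal protein genes rose in 17 of 87, with 23 when adjusted over the list alone (5.32e-04, adjusted p = 0.619 with an estimated correlation). In the RNAi machinery list 1 of 21 members rose and 6 fell, 1 and 8 when adjusted over the list alone, among them Ago2 (129.8 to 78.3 CPM, -0.74 ± 0.21), Tnrc6b (-1.37) and Tut7 (-1.23; camera 0.0386, adjusted p = 0.454 with an estimated correlation). The 12 largest rises by rule began with those of the pseudogene Rps2-ps5 (3.77), Pfn1 (3.48), Fh1 (3.13), Gnb2 (2.79), Iscu (2.71), Pxdc1 (2.66) and Cyp2e1. After these came Gch1 (2.34), the pseudogene Rpl9-ps4 (2.25), Cd14 (2.22) and Tinagl1 (2.15), with the promoter-sharing transcript Ndufb1-ps (2.14). The falls were Apob, Bod1l (-2.45), the nuclear envelope gene Syne2 (-2.44), Kcnq1ot1 (-2.43), the small nucleolar RNAs Snord89 (-4.56) and Snora81 (-3.42), and 6 pseudogenes led by Mup-ps17 (-4.54) and Hspa9-ps1 (-4.45). Several of these moved by over 1.5 times with 1 library at 2 µM. Without replicate 1 Pfn1 stood at 4.73, Fh1 at 3.87, Gnb2 at 3.53 and Snord89 at -5.52, and without replicate 2 Mup-ps17 at -5.93. Without replicate 3 Pfn1 stood at 2.73, Snord89 at -3.76, Mup-ps17 at -3.43 and Snora81 at -2.69. Of the 1239 genes 210 were predicted genes and 215 pseudogenes. Of 84 named genes 29 passed whichever library was left out, Ccl2, Mt1, Fga, Alb and Apob among them. The count was 691 and 549 without Reference 4 0.2 µM replicates 1 and 2, and 631 and 208 without Reference 4 2 µM replicates 2 and 3. Mitochondrial ribosomal RNA took 2.70% of CPM at 0.2 µM and 0.767% at 2 µM. On the first principal component of log2(CPM + 1) the mean scores were -28.7 ± 5.64 and 29.0 ± 12.2. The libraries held 14158740 to 14971332 reads at 0.2 µM and 18802476 to 32927430 at 2 µM. How much of the change follows from dose rather than from these differences between libraries was not tested.

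At 2 µM against 0.2 µM of TTR-1236, 13 genes were lower and 0 higher, and with TTR-1186 0 genes differed. The TTR-1236 groups also had mean scores of -0.915 ± 6.93 and 35.8 ± 12.5 on the first principal component, at 0.2 and 2 µM. The part of dose in these calls was not tested apart from that difference. With TTR-1236 the dynein heavy chain gene Dync1h1 fell from 385 ± 86.3 to 198 ± 44.1 CPM (log2 difference -0.95 ± 0.19, adjusted p = 0.0470), and Resf1 (-2.24), Baz2b (-2.03), Golga4 (-2.01), Atxn2 (-1.96), Birc6 (-1.60), the mitochondrial transfer RNA mt-Tl1 (-1.40), the pseudogenes Hspa9-ps1 (-2.88) and Tmed10-ps (-2.78) and 4 predicted genes fell too. Acute phase genes ranked higher at 2 µM (23 of 28, camera adjusted p = 3.57e-06, adjusted p = 0.0968 with an estimated correlation), as did ribosomal proteins (70 of 87, 2.53e-09, adjusted p = 0.216 with an estimated correlation) and hepatocyte genes (23 of 36, 0.0335, adjusted p = 0.0968 with an estimated correlation). RNAi machinery genes (16 of 21, 0.0495, adjusted p = 0.476 with an estimated correlation) and mitochondrially encoded mRNAs (12 of 13, 0.00671, adjusted p = 0.580 with an estimated correlation) ranked lower. None of the 9 named genes passed whichever library was left out, edgeR called 0 genes and DESeq2 118, and 1112 had an unadjusted p under 0.05. The count was 0, 0 and 1 without TTR-1236 0.2 µM replicates 1, 2 and 3, and 97 and 1 without TTR-1236 2 µM replicates 1 and 3. For TTR-1186, 1415 genes had an unadjusted p under 0.05, edgeR called 0 and DESeq2 54, and limma called 2 without TTR-1186 2 µM replicate 1. Its ribosomal protein genes ranked higher at 2 µM (69 of 87, camera adjusted p = 4.56e-10, adjusted p = 0.535 with an estimated correlation), with 30 risen and 1 fallen when adjusted over the list alone, Rpl22 from 279 to 461 CPM among them.

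The size of the dose response was compared between agents by interaction, and 0 genes passed in any of the 3 tests in limma or in edgeR. At an unadjusted p under 0.05 there were 914 genes for TTR-1236 less Reference 4, 874 for TTR-1186 less Reference 4 and 658 for TTR-1236 less TTR-1186, and DESeq2 called 66, 25 and 0. Leaving out 1 library gave up to 79 genes in the first, without TTR-1236 2 µM replicate 2, and 40 without Reference 4 2 µM replicate 1. The second gave 1 gene without Reference 4 0.2 µM replicate 3, Reference 4 2 µM replicate 2, TTR-1186 0.2 µM replicate 3 or TTR-1186 2 µM replicate 2, and the third 3 genes without TTR-1236 2 µM replicate 2.

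Libraries also differed within groups. The first principal component of log2(CPM + 1) held 31.9% of the variance, and libraries with a high score had a low share of mitochondrial ribosomal RNA. PBS replicate 3 scored 13.9 and had 0.797%, while PBS replicates 1 and 2 scored -33.8 and -24.5 and had 3.26% and 2.70%. TTR-1186 2 µM replicate 2 scored 34.6, had 0.622%, and listed 109 genes at 0.

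**Figure D4:**
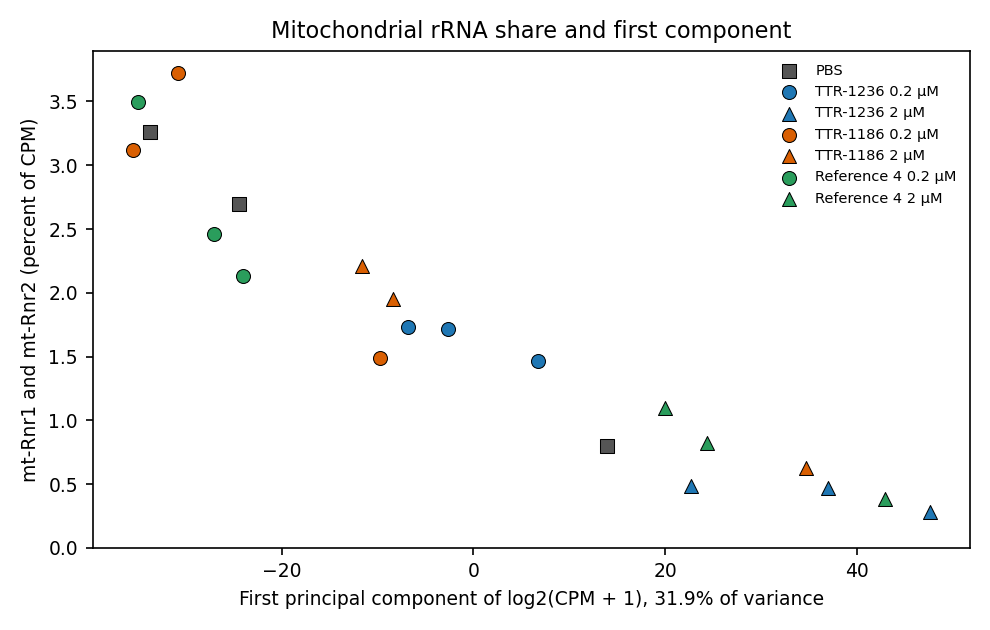
Share of mt-Rnr1 and mt-Rnr2 in all CPM (percent) against the first principal component of log2(CPM + 1), which holds 31.9% of the variance; points are the 21 libraries. The TTR-1236 and Reference 4 libraries at 2 µM lie at the right with low shares, and PBS replicate 3 (13.9, 0.797%) lies apart from the other two PBS libraries.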

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

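Whether Ttr passed the threshold changed in 0 of 337 fits over all comparisons, its log2 fold changes against PBS stayed between -8.49 and -6.59, and no call reversed. The uncalled difference of Ttr between TTR-1236 and TTR-1186 at 0.2 µM did change sign, with a lowest value of -0.12. So did its 3 uncalled interactions of dose and agent, which ran from -0.33 to 0.49 (TTR-1236 less Reference 4), -0.39 to 0.56 (TTR-1186 less Reference 4) and -0.35 to 0.35 (TTR-1236 less TTR-1186). Of the readings of named genes in other fits 14707 stayed on the same side of the threshold, 973 lost their call and 354 gained one. The 14707 include readings called in neither fit, so they do not measure how many calls held. The counts of genes past the threshold were far less steady: 117 of them moved by over 1.5 times or to or from 0, and 220 did not. The cause was not tested. Much of the movement came with single libraries, above all PBS replicate 3, without which every count against PBS rose. The count model mattered too, since DESeq2 called more genes than limma in every comparison with PBS. Ttr itself rested on 59 to 585 reads in a treated library, and whether depth limits the calls of other low genes was not tested. Over all genes the replicate numbers did not pair the libraries. Residuals of libraries with the same number correlated between -0.39 and 0.29 over 63 pairs, and 7 of 21 libraries correlated best with their own number. At 0.2 µM, however, Ttr was lowest in replicate 3, at 5.25 CPM (TTR-1236), 3.19 CPM (TTR-1186) and 4.99 CPM (Reference 4). At 2 µM it was lowest in replicate 3 of TTR-1236 (7.77 CPM) and Reference 4 (12.9 CPM) and in replicate 1 of TTR-1186 (7.59 CPM). An effect of the replicate number on Ttr is therefore not excluded, and the main fit left it out. With the replicate number as a block the count was 1 for TTR-1236 at 0.2 µM against PBS, 3 for TTR-1186 at 2 µM against PBS, 50 for TTR-1236 against TTR-1186 at 2 µM, 44 for TTR-1236 at 2 against 0.2 µM and 11 for the treated mean.

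Leaving out 1 library at a time gave these lowest and highest counts. Against PBS they were 1 and 63 (TTR-1236 at 0.2 µM), 46 and 1588 (TTR-1236 at 2 µM), 3 and 41 (TTR-1186 at 0.2 µM), 1 and 37 (TTR-1186 at 2 µM), 2 and 175 (Reference 4 at 0.2 µM), 6 and 1272 (Reference 4 at 2 µM), and 3 and 639 for the treated mean. At 0.2 µM they were 0 and 18 for TTR-1236 against Reference 4 and 0 and 2 for TTR-1186 against Reference 4, and at 2 µM 2 and 48 for TTR-1186 against Reference 4 and 1 and 181 for TTR-1236 against TTR-1186. For 2 against 0.2 µM they were 0 and 97 (TTR-1236), 0 and 2 (TTR-1186) and 208 and 1148 (Reference 4), and for the interactions 0 and 79, 0 and 1, and 0 and 3.

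DESeq2 on recovered reads called, against PBS, 14 and 1044 genes for TTR-1236 at 0.2 and 2 µM, 21 and 26 for TTR-1186, 88 and 728 for Reference 4 and 111 for the treated mean. It called 238 for TTR-1236 against Reference 4 and 3 for TTR-1236 against TTR-1186 at 0.2 µM, and at 2 µM 1 for TTR-1236 against Reference 4, 127 for TTR-1186 against Reference 4 and 306 for TTR-1236 against TTR-1186. For 2 against 0.2 µM it called 118 with TTR-1236 and 54 with TTR-1186, and 66 and 25 in the interactions with Reference 4. By edgeR with TMM factors the moved counts were 1 (TTR-1236 at 0.2 µM against PBS), 5 and 3 (TTR-1186 at 0.2 and 2 µM against PBS) and 0 (TTR-1236 at 2 against 0.2 µM), and with DESeq2 size factors 1, 5 (TTR-1186 at 0.2 µM) and 0. By limma on TMM-scaled CPM they were 1 for TTR-1236 and 5 for TTR-1186 at 0.2 µM against PBS and 12 for the treated mean. Genes with a mean of at least 10 CPM gave 9 for TTR-1186 at 0.2 µM against PBS and 4 for TTR-1236 at 2 against 0.2 µM. A pseudocount of 0.5 gave 1 for TTR-1236 at 0.2 µM against PBS, and 1 of 5 gave 0 for TTR-1236 at 2 against 0.2 µM.

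Fits on only the libraries compared called, against PBS, 1 and 22 for TTR-1236 at 0.2 and 2 µM, 1 and 1 for TTR-1186, and 2 and 40 for Reference 4. They called 499 for TTR-1236 against Reference 4 at 0.2 µM, 19 for TTR-1236 against TTR-1186 at 2 µM and 190 for TTR-1236 at 2 against 0.2 µM. Without PBS replicate 3 and TTR-1186 2 µM replicate 2, the pair farthest from their group means, the counts against PBS were 150 and 1914 (TTR-1236), 88 and 9 (TTR-1186), 275 and 1571 (Reference 4) and 869 (treated mean), with 233 for TTR-1186 against Reference 4 and 553 for TTR-1236 against TTR-1186 at 2 µM, 242 for TTR-1236 at 2 against 0.2 µM and 4 in the interaction of TTR-1186 and Reference 4.

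With an estimated correlation 0 lists were called except 1 at 2 µM of Reference 4 against PBS, 3 for TTR-1186 against Reference 4 and 1 for TTR-1236 against TTR-1186, both at 2 µM. Fry called, against PBS, 0 and 0 lists for TTR-1236 at 0.2 and 2 µM, 3 and 2 for TTR-1186, 3 and 2 for Reference 4 and 0 for the treated mean, where camera called 5 and 1, 3 and 5, 2 and 5, and 6. In the 3 comparisons of agents at 0.2 µM fry called 0. At 2 µM it called 0 for TTR-1236 against Reference 4 (camera 3), 3 for TTR-1186 against Reference 4 (camera 5) and 2 for TTR-1236 against TTR-1186 (camera 2). For 2 against 0.2 µM it called 1 for TTR-1236 (camera 5), 1 for TTR-1186 (camera 1) and 5 for Reference 4 (camera 4). With the replicate number as a block camera called 4 lists rather than 5 for TTR-1236 at 2 against 0.2 µM, and as many as before in every other comparison. With sites of 6 bases instead of 7 the permutation p of the Ttr sites became 0.001 for TTR-1236 at 0.2 and 2 µM and Reference 4 at 0.2 µM, the smallest that 1000 draws can give. The simulations covered sites of 7 bases only, so these p-values are not interpreted.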

Other observations

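The tests of loss of Ttr itself, of base composition and strand pairing at the Ttr site, and both tests of Ttr by dose were chosen after the result was seen; those of the library axis, of transcript length and of splits were written before.

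At 2 µM, TTR-1236 and Reference 4 moved many genes the same way while TTR-1186 moved few, although every agent left a mean of less than 1% of Ttr at both doses. This contrast of counts depends on single PBS libraries. Without PBS replicate 1 the counts were 49, 6 and 1 for TTR-1236, Reference 4 and TTR-1186, and without PBS replicate 2 they were 46, 9 and 4. Long transcripts such as Apob under both, Golga4 under TTR-1236 and Bod1l under Reference 4 fell, and some short ribosomal protein mRNAs rose. Across genes, log2 fold change and transcript length had a rank correlation of -0.338 and -0.337 for these agents and -0.290 for TTR-1186 at 2 µM.

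The calls at 2 µM of TTR-1236 and Reference 4 might reflect library quality rather than a response of the cells, so 2 explanations of that kind were tested. After subtracting the main axis along which libraries of the other groups differ, a median 0.865 of the log2 fold change of the called genes remained. After removing a trend on transcript length in each library it was 0.836. That axis held 29.9% and 28.4% of the spread within those groups and correlated with the fold changes at 0.422 and 0.301 in size. Subtracting this 1 axis thus took away a minor part of the change of the called genes. Genes that vary little within groups are called more readily, which favours a high remaining share. The axis was also taken without the PBS libraries, so it need not hold how PBS replicate 3 differs. The first principal component of all libraries, with mean scores of -14.8 in PBS and 35.8 and 29.0 in these groups, was not removed. Library quality is therefore not excluded. After the axis 852 and 707 genes were called, 530 and 217 of them among the original 611 and 217, and after length 331 and 63, with 287 and 58 among the original. Loss of Ttr would be shared by TTR-1186 at 2 µM, where a median of 0.362 of the fold change was seen (quartiles 0.212 and 0.541). The genes were chosen for passing with the other agents, which lowers that share. The TTR-1186 mean also joins replicate 2, with a score of 34.6 on the first component, to replicates 1 and 3 with -8.35 and -11.6. Because of that choice of genes and that replicate, the share cannot show that TTR-1186 changed these genes less. How much of the pattern loss of Ttr could explain is not settled. Simulated unchanged groups reached the real counts in 4 and 3 of 100 draws.

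In cells given TTR-1186, genes with CTCTATA in the 3′UTR, a sequence at position 73 of the 583 bases of the Ttr 3′UTR, were lower against PBS, with the lowest z of 16362 7-mers at both doses (-5.24 and -5.96; 633 genes; mean differences -0.09 and -0.11). The lowest z of the Ttr 7-mers was tested by permutation in every comparison of an agent with PBS, without adjustment over the comparisons. For TTR-1236 the permutation p was 0.659 at 0.2 µM and 0.649 at 2 µM, and for Reference 4 0.373 and 0.744. For TTR-1186 it was 0.001 at both doses, the smallest that 1000 draws can give. Those draws leave out the 7-mers of Ttr and give too low a p. Draws from all 7-mers gave 0.0360 at both doses. As the site has the lowest z of all, such a draw is as low only when it holds the site itself. That p therefore does not measure how low the z is. Ttr holds 1116 of the 16362 7-mers, so with equal chances the lowest z falls on 1 of them in 6.82% of cases. Both doses also share the PBS libraries. The site kept rank 1 after the axis was subtracted and ranked 2 in TTR-1186 against TTR-1236 at 2 µM, where 0.476% of 7-mers with the same bases, the site itself alone of 210, were as low, and its other ranks between agents were 22 against TTR-1236 and 209 against Reference 4 at 0.2 µM and 26 against Reference 4 at 2 µM. Against PBS it ranked 39 (z -3.20) at 0.2 µM and 3406 (z -1.20) at 2 µM of TTR-1236, and 23 (z -2.75) and 459 (z -2.62) with Reference 4. At 2 µM the site lay in 50 of 380 genes called lower with TTR-1236 (13.2%), 23 of 138 with Reference 4 (16.7%) and 1 of 3 with TTR-1186. It lay in 7.40% of all genes searched, and these shares are not corrected for UTR length. Jak1, lower with every agent, holds 1 site. At 0.2 and 2 µM its log2 fold changes were -0.67 and -1.12 with TTR-1236, -0.64 and -1.06 with Reference 4, and -0.55 and -0.80 with TTR-1186. The pattern with TTR-1186 could come from a strand complementary to Ttr pairing with other mRNAs as a microRNA does, which stays a hypothesis. The shared PBS libraries cannot give the ranks between agents. Those at 0.2 µM, however, reuse the TTR-1186 libraries in which the site was picked. Those at 2 µM reuse the TTR-1186 libraries of the 2 µM comparison with PBS, and the site was not ranked with single libraries left out. A shift peculiar to the TTR-1186 libraries could thus give such ranks. The site was also low with the other agents at 0.2 µM.

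Ttr was higher at 2 µM than at 0.2 µM in 3 of 3 agents, by a pooled log2 difference of 0.60 (95% interval 0.10 to 1.10). An exact permutation of doses within agents gave a two-sided p of 0.0458, chosen after the rise was seen, while limma gave an adjusted p of 0.0842. Neither took account of the replicate number. Reads carried over from PBS libraries in equal number to each library would give -0.33, the opposite sign. The same pooled comparison in limma called 1821 genes, Ttr not among them. Mean scores on the first principal component were also higher at 2 µM in each agent. They were 35.8 against -0.915 with TTR-1236, 4.90 against -25.4 with TTR-1186 and 29.0 against -28.7 with Reference 4. The permutation cannot tell dose from such a difference between libraries. The rise may therefore be real, a chance result of 9 libraries against 9 or part of that difference, and its cause was not tested.

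Each count was also compared with splits of the same libraries, the real one included, and 10 splits are too few for a share under 0.05. The real grouping was alone in its count, 1 of 10, for TTR-1236 at 0.2 µM (2 genes, highest other 0) and 2 µM (611, 83) and Reference 4 at 0.2 µM (16, 0) and 2 µM (217, 18) against PBS, TTR-1186 against Reference 4 at 2 µM (36, 0) and Reference 4 at 2 against 0.2 µM (1239, 0). There were 2 of 10 with as many for TTR-1186 against PBS at 0.2 µM (3, 5) and 2 µM (5, 49), TTR-1236 against TTR-1186 at 2 µM (33, 68) and TTR-1236 at 2 against 0.2 µM (13, 15). All 10 splits reached the count of 0 for the 3 comparisons of agents at 0.2 µM (0, 0 in each), TTR-1236 against Reference 4 at 2 µM (0, 3) and TTR-1186 at 2 against 0.2 µM (0, 0). For the treated mean 7 of 100 splits called at least its 7 genes, the highest 538, so that count could arise from an arbitrary grouping. Splits with several times the real count, such as 49 against 5 with TTR-1186 2 µM replicates 1 and 2 beside PBS replicate 3, point to a structure of the samples that is not their treatment.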
